A study of Oryza sativa with 6 samples.

How the data were processed

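Genomic DNA of rice seed integument, the maternal outer tissue of the ovule that becomes the seed coat, was profiled by whole-genome bisulfite sequencing in 2 groups of 3 libraries, before and after pollination. Bisulfite turns unmethylated cytosine into a base read as thymine and leaves methylated cytosine unchanged. Per the labels' protocols, the plants were field-grown Nipponbare, DNA was extracted with CTAB and sonicated, fragments of 100 to 500 bp were converted, and paired-end reads of 125 bp were made on an Illumina HiSeq. The labels give both groups the same growth protocol, which tells of mature pistils taken before heading, so how the integument after pollination was collected is not given in the sources used here. Bismark is named in the submitters' processing notes, without a version. The genome build, the coverage behind each level, the cytosine context (CG, CHG or CHH) and any filter are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

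The tables analysed hold 1 row per gene part, namely the 2 kb upstream of a gene, the gene, the 1 kb downstream, and single 5' and 3' UTR intervals. Each part has a table named Hyper and a table named Hypo. Both list the same intervals, so the names are not directions of change, and what they measure is not given in the sources used here. The level of an interval is a fraction from 0 to 1 in the deposited tables, per the file headers 1 value per library and the authors' mean of each group. The denominator of this fraction is not stated. The deposited tables also give the authors' p-value and an adjusted p-value per interval. For 53990 upstream intervals above 0 and covered in all 6 libraries, the authors' p matched an equal-variance or an unequal-variance comparison of the 6 levels within 1% in 97.5% of cases. The deposited adjusted p, headed as a Bonferroni correction, equalled p times the number of intervals divided by the rank within 1% in 100% of intervals. Intervals at 0 in both groups carried a deposited p between 3.12e-08 and 0.000101. Their differences are 0, so they were left out wherever calls of the deposited tables are counted by direction.

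The 6 library columns of the upstream, gene and downstream tables were used. They name the group and a library label (J01 to J03 before, J04 to J06 after pollination) but not the replicate number of the sample labels, so libraries could not be matched to replicate numbers. In all, 36 columns of values per library were not used. They belong to the UTR tables, where text marks fill part of the cells, and to 2 exon tables, of which 1 has no header and 1 names its columns differently. For UTR intervals the authors' means were used, with no SD or n. No 2 libraries were copies of one another, since at most 2.6% of the gene intervals had the same level in any pair within a group.

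The depth behind each level is unknown, so no counting interval of a level can be given. Intervals covered in at least 2 libraries of each group and above 0 in at least 1 library were tested. Those were 54093 upstream, 46348 gene and 48031 downstream intervals out of 55801 per part. Levels were transformed by the arcsine of their square root and fitted with limma 3.58.1 in R 4.3.3, with a variance trend and Benjamini-Hochberg adjustment at 0.05. The design had assumed lists of selected regions or read counts. As the tables hold levels of all intervals, limma became the test. It was not named in the design and was chosen after the files had been seen. Group means of library-wide levels were compared by two-sided exact permutation tests, for which 3 against 3 libraries allow no p under 0.1, with adjustment within each family. Shares of intervals have exact Clopper-Pearson 95% intervals, which cover counting error only, and were compared by two-sided Fisher's exact tests with loci as units. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

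The interval test was tried on simulated levels with the real mean of each interval, and 200 intervals of level 0.4 to 0.6 were changed. The spreads were those fitted by limma, dealt at random among intervals and drawn independently. The link between level and spread was thus lost, so the rates below hold for the simulation and need not hold for the real levels. A first version at lower levels, with only the smaller changes, had recovered almost none, and the levels and sizes were changed after that had been seen. Of changes of 0.05, 0% were recovered in each part. Of changes of 0.1, 0% were recovered upstream, 28% in the gene part and 0% downstream, and of changes of 0.2, 74%, 66% and 38%. Of changes of 0.4, 100%, 88% and 100% were recovered. Unchanged intervals gave 10 of all 97 calls upstream, 9 of 100 in the gene part and 3 of 72 downstream. The comparisons, thresholds and main alternatives were fixed before the data were examined, but the choice of limma was not. Because most real differences were smaller than the changes this simulation recovered well, further analyses were added after the data were seen. They are the mean level per 1 Mb window with at least 20 loci, also fitted with limma, classes of mean level over all 6 libraries, loci with against loci without a listed UTR, intervals whose groups did not overlap, differences between gene parts and the levels of the Hypo tables. With 100 of 378 simulated windows changed, the window test recovered 92% of changes of 0.01 upstream, 86% in the gene part and 90% downstream, and 100% of changes of 0.02, with 6 calls among unchanged windows in each part. Simulated windows also had spreads dealt at random and independent of one another, so a shift shared by all windows of a library was not simulated.

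The rule for naming genes, fixed at the same time, took the largest differences upstream and in the gene part in each direction. The identifiers of the tables are not paired with names in the files, and 0 of the 55801 identifiers matched the gene name table of 39387 genes used here (assembly ASM3414082v1). Therefore at most 2 upstream intervals per direction, the largest differences past the limma threshold, are named, by identifier. This narrower rule was set after the files had been seen. The 31 gene lists fixed beforehand rest on gene descriptions and could not be tested, and neither could markers of other tissues. Alternatives covered the threshold, the size of the difference, the scale, the variance trend, centring of libraries on their medians, low levels, averaging, repeated intervals, chromosomes and each library left out in turn.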

Results

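DNA methylation of the rice integument was measured by bisulfite sequencing in 3 libraries before pollination and 3 libraries after pollination. Levels were given for 55801 gene loci on 12 chromosomes in 3 parts, the upstream 2 kb, the gene and the downstream 1 kb, and for UTR intervals. The libraries are numbered here by column order, J01 to J03 before and J04 to J06 after pollination, which matches no number of the sample labels. Of these loci, 24950 had at least 1 UTR interval in the UTR tables and 30851 had none. Between 168 and 409 intervals per library and part were marked as not covered. The read depth behind a level is unknown, and the number of libraries limits the precision. Both groups carry the same growth protocol, of pistils taken before heading, so the meaning of after pollination rests on the group labels alone. The comparison asks whether and where the methylation of the integument changes after pollination.

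Methylation was lower after pollination in all 3 gene parts, and the gap of the mean level was wider in the flanks than in the genes. Upstream, the mean level was 0.175 ± 0.00119 (SD, n = 3) before and 0.149 ± 0.0017 (SD, n = 3) after pollination, a difference of -0.0257 and a ratio of after to before of 0.853. In the gene part it was 0.154 ± 0.000663 and 0.141 ± 0.00263, a difference of -0.0121 and a ratio of 0.921. Downstream it was 0.155 ± 0.000841 and 0.132 ± 0.00177, a difference of -0.0223 and a ratio of 0.856. Every library after pollination lay below every library before it in each part. The library labelled J04 had the lowest mean in each part (0.138 in the gene part, against 0.143 in both J05 and J06), and its gene levels correlated less with J05 and J06 (Pearson 0.935 and 0.936) than those of J01 with J05 (0.945). Without J04 the gene difference was -0.0106. The excess of the upstream over the gene level shrank from 0.0214 ± 0.000533 to 0.00769 ± 0.001, also without overlap of the libraries. Before pollination the downstream level exceeded the gene level by 0.000996 ± 0.000327, and after pollination the downstream minus gene difference was -0.00922 ± 0.000899. Each of these differences exceeded the spread between libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow (0.106 after adjustment over 18 comparisons). A p under 0.05 could not be reached by this test.

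**Figure D1:**
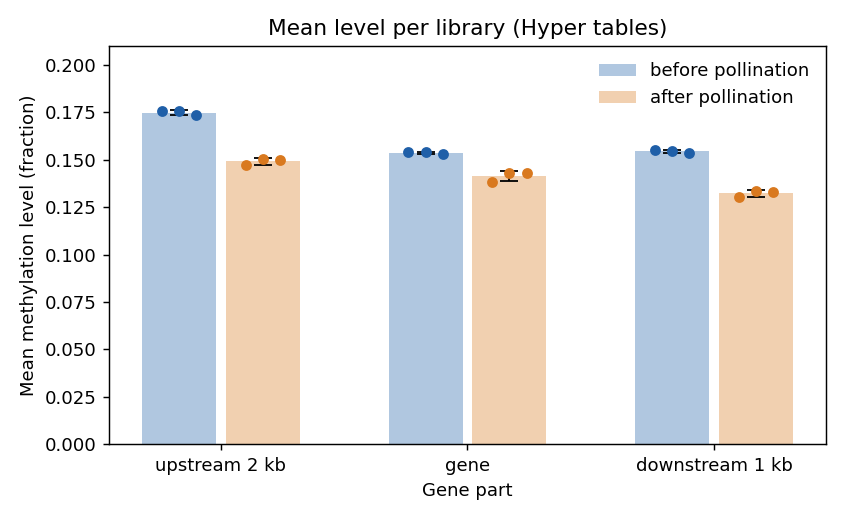
Mean methylation level (fraction) of all covered intervals per gene part. Bars are group means, error bars the SD of 3 libraries and points single libraries, and in each part the 3 libraries after pollination lie below the 3 before it, as upstream at 0.149 against 0.175.

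The lower level of the gene parts extended over all 12 chromosomes. On each of the 12 chromosomes every library after pollination lay below every library before it in all 3 parts, with ratios of after to before from 0.825 to 0.869 upstream, from 0.91 to 0.929 in the gene part and from 0.823 to 0.873 downstream. In windows of 1 Mb, the level fell in 378 of 378 windows upstream, in 367 of 378 in the gene part and in 378 of 378 downstream, and rose in 0 (limma with Benjamini-Hochberg adjustment; 0 were higher at an unadjusted p under 0.05). The gene windows that did not pass also had lower means after pollination. The widest upstream gap was on chromosome 9 from 15000001 to 16000000, where 133 loci had a mean level of 0.174 ± 0.00124 before and 0.134 ± 0.00246 after pollination (limma adjusted p = 1.03e-13). On chromosome 10 from 19000001 to 20000000 the upstream level of 149 loci fell from 0.148 ± 0.00387 to 0.11 ± 0.000702 (limma adjusted p = 1.03e-13). The narrowest upstream gap was on chromosome 4 from 3000001 to 4000000, with 0.234 ± 0.00104 before and 0.222 ± 0.00296 after (limma adjusted p = 0.000668). The widest gap of the gene part was on chromosome 6 from 8000001 to 9000000, with 0.229 ± 0.00621 before and 0.205 ± 0.00593 after (limma adjusted p = 0.000348). When each library was centred on its median window, 25 upstream windows fell and 118 rose relative to the median, 0 and 0 did so in the gene part (28 and 7 at an unadjusted p under 0.05), and 13 and 33 downstream. Centring subtracts the median window level of each library, so a window that rose here fell less than that median level did. These centred fits used the transformed level, on which an equal fall counts for more at low levels. The window test was chosen after the levels had been seen. It treats windows as independent, although all windows of a library share any shift of that library. The window p-values are thus not evidence from 378 separate places, and the library-wide means gave a two-sided exact permutation p of 0.1.

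**Figure D2:**
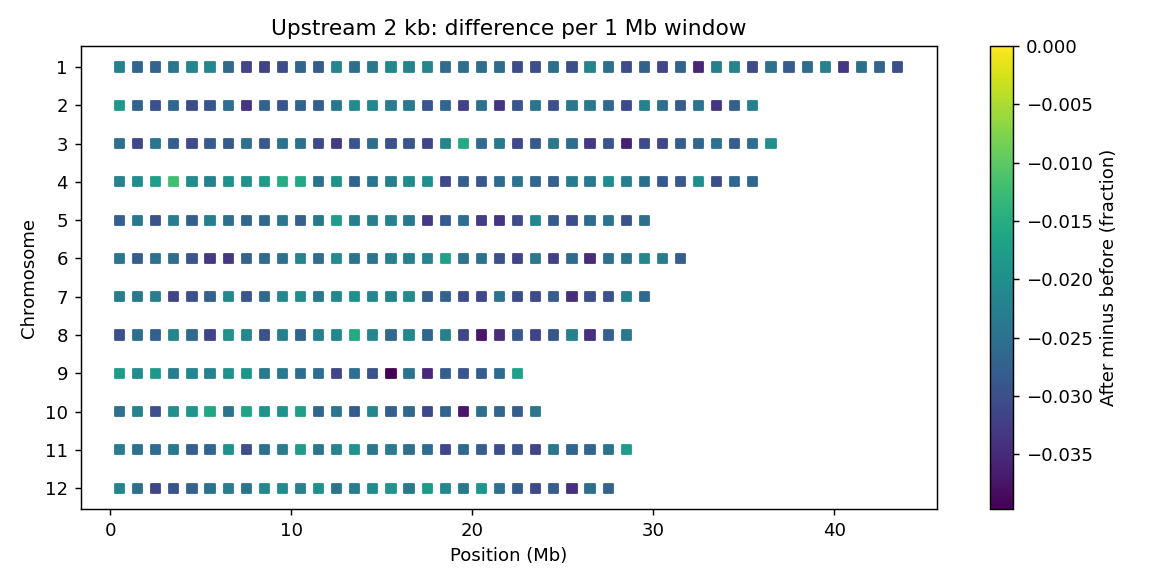
Difference of the mean upstream level, after minus before pollination (fraction, colour), in 378 windows of 1 Mb along the 12 chromosomes (position in Mb). All windows are below 0, from -0.0397 on chromosome 9 to -0.012 on chromosome 4.

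Loci with a listed UTR carried less methylation than loci without one, and their flanks had the wider relative gap after pollination. Upstream of loci with a listed UTR the mean level was 0.14 ± 0.00173 (SD, n = 3) before and 0.111 ± 0.000557 after, a ratio of 0.795, against 0.203 ± 0.000806 and 0.18 ± 0.00266 upstream of loci without one, a ratio of 0.886. Downstream the levels were 0.0995 ± 0.000975 and 0.0774 ± 0.000507 with a listed UTR, a ratio of 0.778, against 0.199 ± 0.000728 and 0.177 ± 0.0028 without, a ratio of 0.887. In the gene part they were 0.0517 ± 0.000599 and 0.0456 ± 0.000256 with a listed UTR and 0.236 ± 0.000814 and 0.219 ± 0.0045 without, with ratios of 0.883 and 0.928. The absolute differences with and without a listed UTR were -0.0288 and -0.0232 upstream, and alike downstream at -0.0221 and -0.0225. In the gene part the absolute difference was narrower with a listed UTR, at -0.00604 against -0.0169. As levels differed between the 2 kinds of loci, they were also compared within classes of the mean level over all 6 libraries. At levels above 0.2 and up to 0.3, the upstream difference was -0.0493 in 3970 loci with a listed UTR and -0.0266 in 8693 loci without. Downstream in the same class the differences were -0.0544 and -0.0279, and in the gene part -0.0241 and -0.0204. The 2 kinds of loci differed by -0.0226 upstream, -0.0265 downstream and -0.00368 in the gene part, each without overlap of the libraries (two-sided exact permutation p = 0.1, the smallest possible, and 0.135 after adjustment over 23 classes). Upstream at levels up to 0.02 they differed by 0.000103 (exact permutation p = 0.6), at levels above 0.02 and up to 0.05 by 0.000467 (exact permutation p = 0.2), and downstream at levels up to 0.02 by 0.000572 (exact permutation p = 0.1). The sign was also the opposite downstream at levels above 0.02 and up to 0.05 (0.000297) and in the gene part at levels up to 0.02 (2.55e-05). In the gene part it was so too above 0.02 and up to 0.05 (0.00273) and above 0.05 and up to 0.1 (0.00526). It was so there as well above 0.4 and up to 0.5 (0.0082). Above 0.3 and up to 0.4 the gene parts of the 2 kinds differed by -0.00121 (exact permutation p = 0.8). Above 0.5 they differed by -0.00578 (exact permutation p = 0.6).

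**Figure D3:**
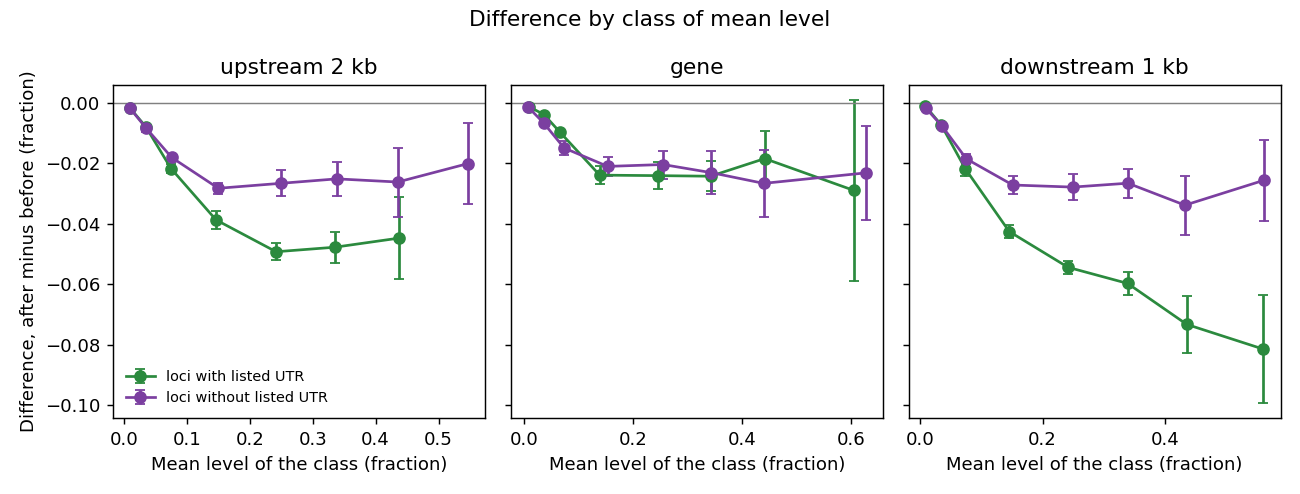
Difference of the mean level, after minus before pollination (fraction), against the mean level of the class (fraction) for loci with and without a listed UTR in 3 gene parts. Points are classes of intervals and error bars the root of the summed squared SDs of the 2 groups of 3 libraries; in the upstream class of 0.2 to 0.3 the points lie at -0.0493 and -0.0266.

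The gap also depended on the level itself. Upstream, the ratio of after to before was 0.837 at levels up to 0.02, 0.764 at levels above 0.05 and up to 0.1, and 0.935 at levels above 0.4 and up to 0.5. Downstream the same classes had ratios of 0.859, 0.76 and 0.912, and in the gene part 0.849, 0.849 and 0.942. The absolute difference grew from -0.0017 in the lowest of these upstream classes to -0.0333 at levels above 0.1 and up to 0.2, and was -0.0337, -0.0294, -0.0291 and -0.0207 in the 4 classes above. Above 0.1 and up to 0.5 the gene part had differences of -0.0218, -0.0207, -0.0231 and -0.0264. Above 0.5 the gene difference was -0.0233 in 1541 intervals, wider than the -0.0207 in 114 upstream intervals.

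Counted by interval, 44573 of 54093 upstream intervals (82.4%, exact Clopper-Pearson interval 82.1% to 82.7%) had a lower mean level after pollination. The share was 76.6% of 46348 gene intervals (76.3% to 77.0%) and 76.3% of 48031 downstream intervals (76.0% to 76.7%). The upstream share exceeded the gene share (Fisher's exact test over loci, odds ratio 1.43, adjusted p = 1.6e-112 over 6 comparisons) and the downstream share (odds ratio 1.45, adjusted p = 1.6e-125), and the gene and downstream shares differed by less than the test could call (odds ratio 1.02, adjusted p = 0.343). Upstream, 84.2% of intervals of loci with a listed UTR and 81.0% of those without were lower (Fisher's exact test, odds ratio 1.25, adjusted p = 1.2e-21). In the gene part the shares over all levels were 72.3% and 80.0% (odds ratio 0.652, adjusted p = 2.22e-83), and downstream 76.6% and 76.2% (adjusted p = 0.346). Levels differ between these loci and the share depends on the level. At levels above 0.1 and up to 0.2 the shares with and without a listed UTR were 85.1% and 79.9% in the gene part and 85.8% and 78.6% downstream, and above 0.2 and up to 0.3 they were 83.3% and 83.3%, and 86.1% and 78.2%. Other gene classes went the other way, with 69.6% and 71.5% above 0.02 and up to 0.05, 68.4% and 75.5% above 0.4 and up to 0.5, and 55.2% and 69.0% above that. These tests treat loci as units and do not measure the spread between libraries. Comparisons between parts also hold largely the same loci on both sides, and this pairing was ignored. Libraries of a group differed more per interval downstream (mean absolute difference 0.0356 to 0.0421) than upstream (0.0291 to 0.0346), and scatter pulls a share toward an even split. A higher share upstream is thus no sign of a larger relative fall, as the ratios of the mean levels were 0.853 upstream and 0.856 downstream. The absolute fall was larger upstream. The excess of the upstream over the downstream level shrank from 0.0204 ± 0.000452 to 0.0169 ± 0.000107 (two-sided exact permutation p = 0.1, the smallest possible). The 3 libraries after pollination lay below all 3 before it in 14026 of 53990 upstream intervals above 0 and covered in all libraries, and above them in 602 (1.12%). These shares were 20.5% and 1.41% in the gene part, and 19.9% and 1.42% downstream. Chance alone gives 5% in each direction, 10% in all. A mean difference beyond 0.2 was rare, with 50 upstream intervals lower and 14 higher, 156 gene intervals lower and 89 higher, and 177 downstream intervals lower and 29 higher. Gene intervals lower by more than 0.2 had a median length of 443.5 bp and those higher by more than 0.2 a median of 432 bp, against 2882 bp for all tested gene intervals.

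The number of loci lower in several parts lay near that of independent lists. Of 45061 loci with both parts covered, 2383 were lower without overlap both upstream and in the gene part, and independent lists of these sizes share 2373. The upstream and downstream lists shared 2469 loci against 2385, and the gene and downstream lists 1672 against 1656. In all 3 parts 407 loci were lower, against 411 for independent lists. Over the other 9 splits of the 6 libraries, the observed number divided by the independent number ranged from 0.902 to 1.17 for the upstream and downstream lists, where the real split gave 1.04. For the upstream and gene lists it ranged from 0.958 to 1.24, with 1.00 for the real split, and for the gene and downstream lists from 1.00 to 1.27, with 1.01. Most other splits of these 2 pairs lay above 1. As each of those splits mixes libraries of both groups, it still holds part of the group difference and gives no value without a change. Whether independent lists are that value thus stays undecided.

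Few single intervals passed the limma test. At an adjusted p under 0.05, 6 upstream intervals fell and 1 rose, 2 gene intervals fell and 0 rose, and 4 downstream intervals fell and 1 rose. At an unadjusted p under 0.05, 10931 upstream intervals were lower and 308 higher, 5730 gene intervals were lower and 338 higher, and 6789 downstream intervals were lower and 346 higher. With libraries centred on their medians these counts became 2284 lower and 5690 higher upstream, 971 and 8905 in the gene part, and 1963 and 4866 downstream. Centring subtracts the median level of each library on the transformed scale, not a difference that all intervals share. As more intervals were higher than lower after it, the median level fell by more than many intervals did. A count of higher intervals after centring thus does not mean a rise. In 13 of the 14 called intervals, all covered libraries of 1 group were listed at 0, and the depth behind these zeros is unknown. The largest fall upstream was at LOC_Os02g40150 (chromosome 2, 24303367 to 24305366, plus strand), from 0.28 ± 0.0133 (SD, n = 2, as 1 library was not covered) to 0 in 3 libraries (limma adjusted p = 0.00782). Downstream of that locus the mean went the other way, from 0.242 ± 0.211 to 0.369 ± 0.0599 (n = 3 each, limma adjusted p = 0.596). Its gene part was covered in only 1 library before and 2 after pollination and was not tested. The next fall upstream was at LOC_Os07g03377 (chromosome 7, 1356149 to 1358148, minus strand), from 0.256 ± 0.0556 (n = 3) to 0 in 3 libraries (limma adjusted p = 0.00907). The upstream interval that rose was at LOC_Os02g38580 (chromosome 2, 23324336 to 23326335, plus strand), from 0 in 3 libraries to 0.068 ± 0.0179 (n = 3, limma adjusted p = 0.0377). On the untransformed level both falls and the rise missed the threshold (limma adjusted p = 0.0646, 0.075 and 0.075), as did the rise without a variance trend (0.0632). Without the library labelled J04 both falls missed the threshold (limma adjusted p = 0.066 each), and without it 0 upstream intervals were called in either direction (8974 lower and 331 higher at an unadjusted p under 0.05). The rise missed the threshold without J01, J02, J03, J04 or J05. The called upstream interval with levels above 0 in both groups was on chromosome 12 from 13782379 to 13784378, where the level fell from 0.421 ± 0.0114 to 0.226 ± 0.0102 (limma adjusted p = 0.0389). On chromosome 9, 4 called intervals, chosen for mention after their values were seen, overlapped in 1 stretch and shared the 450 bp from 14507771 to 14508220, which is the gene interval of 1 of the 4 loci. That gene interval fell from 0.108 ± 0.00331 to 0 in 3 libraries (limma adjusted p = 0.000813). Coordinates are those of the tables, whose genome build is not given in the sources used here.

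The authors' own test gave more calls. In the authors' deposited table of upstream intervals, 2137 had an adjusted p under 0.05, of which 1513 were at 0 in both groups, 616 were lower and 8 were higher after pollination. In the authors' deposited table of gene intervals, 10597 passed, of which 9109 were at 0 in both groups, 1432 were lower and 56 higher. In the authors' deposited table of downstream intervals, 8701 passed, of which 7365 were at 0, 1284 were lower and 52 higher. When the p-values of the authors' deposited tables were adjusted again without the intervals at 0, 3 upstream, 5 gene and 0 downstream intervals passed.

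UTR intervals had low levels, and most of those above 0 were lower after pollination. Of 38869 intervals of the 5' UTR with a value, 32341 were at 0 in both groups, and of 41419 intervals of the 3' UTR, 26817 were. In the authors' deposited tables the mean level of the 5' UTR was 0.0222 before and 0.0208 after pollination, and that of the 3' UTR was 0.0322 and 0.0277. Of the 6528 intervals of the 5' UTR above 0, 59.1% were lower after pollination (exact Clopper-Pearson interval 57.9% to 60.3%), and of the 14602 of the 3' UTR, 60.8% (60.0% to 61.6%). Some intervals are listed more than once, which these intervals of the share ignore. Counted once each, 59.6% of 5404 distinct 5' UTR intervals and 61.1% of 12509 distinct 3' UTR intervals were lower. No spread between libraries was computed for UTR intervals.

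The Hypo tables held almost no level above 0, and the mean of what they held was also lower after pollination. Upstream, 228 of 55801 intervals were above 0 in at least 1 library, in the gene part 168 and downstream 139, with a highest level of 0.0367. The mean level of these intervals was 0.00564 ± 0.000175 (SD, n = 3) before and 0.00464 ± 0.000141 after pollination upstream, 0.00651 ± 0.000522 and 0.00544 ± 0.000119 in the gene part, and 0.00655 ± 0.000417 and 0.00543 ± 0.000227 downstream. The libraries of the groups did not overlap in any of the 3 parts (two-sided exact permutation p = 0.1, the smallest possible). The 2 windows of 1 Mb with the most such upstream intervals had overlapping groups, on chromosome 12 (33 intervals, ratio 0.922, exact permutation p = 0.3) and chromosome 10 (24 intervals, ratio 0.919, exact permutation p = 0.2), as did the chromosome 12 window in the gene part (exact permutation p = 0.4) and downstream (0.2). Of the 228 upstream intervals 187 were lower and 41 higher. With limma, 0 upstream, 1 gene and 1 downstream interval fell and 0 rose, and at an unadjusted p under 0.05, 20, 13 and 10 were lower and 0, 1 and 0 higher.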

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

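The threshold of 0.1, the minimum level, the untransformed level, the fit without a variance trend, centred libraries, the authors' deposited adjusted p, weighting by length, the window test and the comparisons of UTR loci, Hypo levels and parts were added after the files had been seen. The mean difference kept its sign under all settings in which it was computed. Centred libraries were not among them, since centring subtracts the median level of each library. The mean difference was -0.0343 upstream, -0.00921 in the gene part and -0.0309 downstream with the median over intervals, and -0.0302, -0.0196 and -0.031 with the added minimum level of 0.05, which leaves out intervals near 0. Of the comparisons of a value with its main setting, 285 stayed within the spread or within 1.5 times the count. Another 99 moved further, 13 lost their threshold and 0 changed direction. Some settings could hardly move a value, such as length weighting of flanks of fixed length, 1 chromosome left out or repeated intervals counted once. The tally is thus no measure of robustness.

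The share of lower intervals was 85.0% upstream, 81.4% in the gene part and 79.7% downstream with the added minimum level. With differences of at least 0.2 it was 78.1%, 63.7% and 85.9%, and with an adjusted p under 0.01 it was 100% of 3 upstream calls and 100% of 1 gene call. Without single libraries it ranged from 79.6% to 80.9%, from 73.6% to 75.5% and from 73.3% to 75.1%.

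Counts of called intervals were unstable. Under 0.01, upstream calls were 3 lower and 0 higher, gene calls 1 lower, and downstream calls 0 and 0. Under the added 0.1 they were 2024 and 24, 31 and 6, and 54 and 8. With differences of at least 0.2 they were 2 and 0 upstream, 0 lower in the gene part and 1 lower downstream. On the untransformed level they were 0 and 0, 1 lower, and 0 and 0. Without a variance trend 0 higher were left upstream, and 0 and 0 downstream. With centred libraries 3 lower were left upstream and 0 and 0 downstream, and with the minimum level 2 and 0, and 0 and 0. The authors' deposited adjusted p gave 616 and 8, 1432 and 56, and 1284 and 52. Without single libraries the calls ranged from 0 to 6 lower and 0 to 6 higher upstream, from 1 to 6 and 0 to 3 in the gene part, and from 0 to 1 and 0 to 1 downstream. Without the library J04, 0 and 0 were called upstream. The cause was not tested.

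Of the windows of 1 Mb, between 343 and 378 were called lower in each part under the other settings, but with centred libraries 25 were lower and 118 higher upstream, 0 lower in the gene part, and 13 lower and 33 higher downstream. Centring subtracts the change of the median window level, which need not be the change of a typical window. The rise at LOC_Os02g38580 missed the threshold in 9 settings and passed in 3, and both named falls missed it without J04 and on the untransformed level.

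No paired analysis was possible because the library columns carry no replicate number of the sample labels. A minimum of coverage or cytosines, sequence contexts, transposable-element genes, gene lists and their backgrounds, a logistic model of reads and overlap of regions between parts were not run, since the tables give no such values or names. No interval passed under 0.01 downstream, so no share is given there.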

Other observations

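The tests of the lower level by offset, conversion, factor and coverage, the test of the Hypo tables, the splits for single intervals, and the window and UTR comparisons themselves were chosen after the results had been seen. The test of loci at matched levels and the splits of windows were fixed before their own results. The offset and conversion tests are revised versions: earlier ones, on intervals too near 0, on equal differences and on levels above 0.1 only, had been void, of the wrong form or undecided.

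Windows with little upstream methylation had the widest relative, but not the widest absolute, gap after pollination. Windows were parted for each gene part by the level of that part, and in the 126 windows of 1 Mb with the lowest upstream level, the middle 126 and the highest 126, the ratios of after to before were 0.803, 0.841 and 0.896, and the differences -0.0269, -0.0276 and -0.0226. By gene level the gene ratios were 0.903, 0.916 and 0.933, while the gene differences widened with the level (-0.0089, -0.0123 and -0.0152), and by downstream level the downstream ratios were 0.805, 0.842 and 0.897. With libraries centred on the median level of their windows, 18, 7 and 0 of these upstream windows fell more than that median level did. In 5, 18 and 95 the level fell less (limma with Benjamini-Hochberg adjustment). Of those parted by downstream level, 8, 5 and 0 fell more and 0, 2 and 31 less. This fit used the transformed level, on which an equal fall counts for more at low levels, so the scale may make part of this order. No centred fit on the untransformed level was run. Of the gene windows 0 passed with limma after centring (28 lower and 7 higher at an unadjusted p under 0.05).

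For the lower level, one offset in every interval was argued against as the whole cause, since the difference at levels above 0.1 and up to 0.2 exceeded that at 0.05 to 0.1, which leaves room for it, by -0.0108 (SD 0.00217) or more in size in each part. Unequal conversion by bisulfite alone changes the unmethylated share by one factor at every level, if levels are shares of reads over all cytosines. The denominator is not stated, and 1513 upstream and 9109 gene intervals were at 0 in both groups, so this premise stays open. On this premise, conversion alone was argued against in the flanks at matched levels above 0.2 and up to 0.3. There loci with and without a listed UTR differed by -0.0226 (SD 0.00342) or more in size. In the gene part, on the same premise, the argument against it rests on classes of low level. The log ratio of the unmethylated share at 0.1 to 0.2 exceeded that at 0.05 to 0.1 by 0.0138 (SD 0.00263) there. Between 0.1 to 0.2 and 0.4 to 0.5 this log ratio differed by only 0.0214 (SD 0.0177) in the gene part. The flanks had 0.0123 (SD 0.0197) upstream and 0.0309 (SD 0.0149) downstream. Without the premise, conversion alone stays undecided. One factor for every interval, as dilution with unmethylated DNA would give, predicts 1 ratio, but the ratio at levels above 0.4 and up to 0.5 exceeded that at 0.05 to 0.1 by at least 0.0929, which argues against one factor alone. Coverage was tested 2 times: the number of uncovered intervals, after minus before, was -0.444 on average with overlapping groups and decided nothing, and a test added after that outcome found differences between -0.0257 and -0.0121 among intervals covered in all 6 libraries, so different covered intervals cannot be the whole cause. Unequal conversion as part of the difference, or an offset, conversion or a factor joined by a filter of the authors near 0, may contribute. So may the depth within intervals, the way of collection and cells of another tissue with a methylation profile of their own. The change after pollination named by the labels may contribute too, and these cannot be separated here. Any batch that held J01 to J03 apart from J04 to J06 would coincide with the groups and cannot be told apart either.

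Loci with a listed UTR had the wider relative gap in their flanks, and their lower level alone was weighed as the cause. At matched upstream levels above 0.1 and up to 0.2, their difference was still wider by 0.0105 than that of loci without (with minus without, -0.0105), more than 2 times the SD of the difference (0.00196), and also of the 4 group SDs combined as independent (0.00345). A candidate explanation is that flanking sequence of loci with transcript annotation holds another mix of cytosine contexts, which was not tested because contexts are not given.

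Levels above 0 in the Hypo tables were clustered, as the 5 windows of 1 Mb with the most such upstream intervals held 100 of 228, against at most 24 in 10000 random draws of as many intervals. On chromosome 12 between 20450980 and 20704919, 33 upstream intervals had a median Hyper level of 0.000822, against 0.191 for the other intervals of that window, and on chromosome 10 between 10810491 and 10921401, 24 intervals had 0.00549 against 0.194. The median Hyper level of upstream intervals with a Hypo level above 0.002 was 0.00526, below the lowest median (0.106) of 1000 random sets, so these 134 of the 228 upstream intervals lie mostly in sequence with almost no methylation in the Hyper tables. Gene intervals of 2 other windows did not share this, on chromosome 11 between 28542267 and 28621740 (5 intervals, Hyper median 0.271 against 0.0536) and on chromosome 12 between 13345743 and 13408308 (4 intervals, 0.0958 against 0.252). Copies of plastid or mitochondrial DNA in the nuclear genome may have such values, which was not tested, as no genome sequence was used here.

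The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For single intervals, the real split called 7 upstream against a highest other count of 6, so 1 split reached the real count. In the gene part it called 2 against 5, and 7 of the 10 splits called as many, and downstream it called 5 against 10, and 2 splits did. For windows of 1 Mb, the real split called 378 upstream, 367 in the gene part and 378 downstream, and the highest count of the other splits was 0 in each, so that 1 split of 10 reached the real count. Every other split puts libraries of both groups on each side, so a difference between the groups widens its spread and lowers its count. These counts are thus no value without a change, and nothing is concluded from 378 against 0.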
